A study of Rattus norvegicus with 24 samples.

How the data were processed

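Whole hippocampal RNA of 24 rats was measured on Illumina rat expression arrays, 1 array per animal. Per the series' design text, growth hormone (GH)-deficient dwarf rats (dw/dw) and heterozygous controls (HZ) were used, and each group at each time point held 4 animals. From postnatal day 35 the dw/dw rats received subcutaneous injections of 300 µg GH or saline for 7 or 30 days, and the HZ rats received saline, so that the animals were 42 or 65 days old when the tissue was taken. Each array was placed in its group by its source label, which names the tissue, genotype, treatment and duration. The 12 arrays of the 7-day time point lay on one slide and the 12 arrays of the 30-day time point on another, per the labels. On both slides the dw/dw saline arrays held positions 1 to 4, the dw/dw GH arrays positions 5 to 8 and the HZ arrays positions 9 to 12.

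Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase on columns, checked on a Bioanalyzer, copied into biotin-labelled cRNA and stained with Cy3-streptavidin. GenomeStudio 2010.2 is named in the submitters' processing notes, with no role given. The deposited table of scanner output holds, per the file headers, an average bead signal (an intensity on a linear scale) and a detection p-value for each of 22226 probes on each array. The lowest deposited signal intensity was 27.2 and no background subtraction or normalization between arrays was visible in the values. The authors' series matrix holds a second set of intensity values for the same arrays, whose scale and normalization are not given in the sources used here. From the values, these were on a linear scale, background-subtracted (lowest value -13.04), and not centred per gene. All 12 arrays of the first slide shared the maximum 14653 and all 12 of the second the maximum 12626, as quantile normalization within each slide would give, but the method is not stated. The medians of their columns centred on 9.77 on the first slide and 8.61 on the second. Each column followed the rank order of its own scanner column, with a Spearman correlation across probes of at least 0.9999972. These values served as an alternative only, on a log2 scale with values under 1 set to 1. Between 31.8% and 32.1% of all probes on an array lay under 1.

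The scanner signals were corrected for background with normexp, using the detection p-values in place of negative control probes, with an offset of 16, quantile normalized over all 24 arrays and put on a log2 scale (neqc in limma 3.58.1, R 4.3.3, with jsonlite 2.0.0 to read the labels). The offset draws log2 differences of dim probes towards 0. A probe was tested when its detection p-value was under 0.05 on at least 4 arrays, which kept 11487 probes (51.7%). Of all probes, 13192 carried 1 gene symbol in the annotation table used here, 0 carried several and 9034 were unnamed here. Of the named probes, 13151 were matched by gene ID to the RefSeq gene table of assembly GRCr8, and 0 symbols needed an update. Of the tested probes 8050 were named, for 7983 genes, and 3437 were unnamed here. For the 67 genes with more than 1 tested probe, the probe with the highest mean value over all arrays stood for the gene. No genome coordinates are given, because the reference gene table is not the build of the array's design.

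Depth cannot be counted on arrays, and the number of arrays limits the precision. Between 44.9% and 51.2% of the probes were detected on an array, and the median signal lay between 46 and 56.7.

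A linear model with the 6 group means was fitted to all 24 arrays with lmFit, leaving 18 residual degrees of freedom, and moderated with eBayes (prior degrees of freedom 1.55). All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the tested probes of each comparison, with a threshold of 0.05. The 10 comparisons were dw/dw saline against HZ saline, dw/dw GH against dw/dw saline and dw/dw GH against HZ saline at each time point, the change of the deficiency effect and of the GH effect from 7 to 30 days (interaction contrasts), HZ saline at 30 against 7 days, and the mean of the 4 dw/dw groups against the mean of the 2 HZ groups. The array values carry no unit of molecules, so a fold is 2 to the power of the log2 difference of normalized signals.

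Before the data were examined, 33 gene lists were fixed, 18 of pathways and 15 of markers of cell types and neighbouring tissues. Each was tested in the 6 comparisons within a time point with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, and with fry. P-values of list tests were adjusted over the 33 lists within a comparison. The same tests for the comparisons that join both time points were added after the data were seen. A list score is the mean over its members of the log2 value minus the gene's mean over all arrays, compared between groups by an exact permutation test, for which 4 against 4 arrays give a smallest possible p of 0.029. The rule for genes named in the text was also fixed then. It named Igf1, Igf1r, Ghr, Socs2 and Cish wherever they were tested. It added up to 10 genes with the largest rise and up to 10 with the largest fall among probes past the threshold whose groups of arrays did not overlap. Where fewer than 10 probes passed, it took the 5 named probes with the smallest p in each direction, and of each list it took up to 4 members with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

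Correlations across probes between fold changes that share arrays were set beside 1000 simulated draws of unchanged groups sharing the same arrays, and were recomputed with the shared dw/dw saline arrays split 2 and 2. The fit was tested on simulated data in which 200 of the 11487 probes were changed. Each draw mixed changes of 0.25, 0.5 and 1 log2, and the larger changes ease the adjusted threshold for the smaller ones. The shares recovered therefore do not apply to data in which few probes differ. For dw/dw GH against dw/dw saline at 7 days, it recovered 75.5% of changes of 0.25 log2, 96.3% of 0.5 and 99.6% of 1. For dw/dw saline against HZ saline at 30 days the shares were 73.6%, 96.7% and 99.7%, and for HZ saline at 30 against 7 days 73.4%, 96% and 99.8%. In simulated lists of 15 genes for dw/dw GH against dw/dw saline at 7 days, a shift of 0.2 log2 was called in 100% of draws and an unshifted list in 1%, with the preset and with the estimated correlation. The members of these lists were drawn at random from the tested probes. Neither the 100% nor the 1% therefore applies to lists whose members move together from array to array.

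The alternatives tried were no background correction, median scaling in place of quantile normalization, an offset of 50, the authors' series matrix values, no filter and a stricter filter on detection (p under 0.01 on all 4 arrays of a group), each time point normalized and fitted alone, array weights, a trended and robust eBayes, the position on the slide as a covariate, the replicate number as a block, and each array left out in turn. The share of probes detected as a covariate, the 3 arrays numbered 1 at 30 days left out together, and the list tests without each array were added after the data were seen. An enrichment by chromosome was planned for probes past the threshold of the genotype comparison, of which there were 0 in the limma fit, so it was run on the probes at an unadjusted p under 0.05 instead. The share of these with a known chromosome lay below the minimum that the plan set for running this test.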

Results

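Gene expression in the hippocampus was compared between GH-deficient dwarf rats, saline or GH treated, and heterozygous controls after 7 and after 30 days of treatment. The dw/dw strain carries a recessive dwarfism with low pituitary GH output, and circulating GH drives liver production of insulin-like growth factor 1 (IGF-1). The series asks how this endocrine axis bears on hippocampal gene expression during adolescence. There were 6 groups of 4 rats, and every value below is a normalized log2 signal with its SD over 4 animals, or a log2 difference with its SE from the limma fit over all 24 arrays. Between 44.9% and 51.2% of the probes were detected on each array. Because each time point was hybridised on its own slide, age and slide could not be told apart. Because each group held the same block of positions on both slides, group could not be told apart from a position effect shared by a block. Only a linear trend along the positions could be fitted as a covariate. Group differences are less precise in that fit, so a lost call or turned sign there decides nothing. Probes with a log2 signal near 6.1 lay close to background, where differences are compressed.

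Genes of the GH and IGF axis did not pass the adjusted threshold in any of the 6 comparisons within a time point. Igf1r, the IGF-1 receptor, was detected on 24 arrays, and its signal was 6.87 ± 0.07 in HZ, 6.90 ± 0.09 in dw/dw saline and 6.89 ± 0.12 in dw/dw GH rats at 7 days (SD, n = 4). At 30 days the values were 6.97 ± 0.04, 7.08 ± 0.09 and 7.02 ± 0.07, and the difference between dw/dw saline and HZ was 0.12 (SE 0.059, limma adjusted p = 0.69). Socs2 and Cish, feedback inhibitors of cytokine receptor signalling that GH induces through STAT5, were dim, with detection on 20 and 6 arrays. Their GH minus saline differences in dw/dw rats at 7 days were -0.0023 (SE 0.018) and 0.015 (SE 0.0097), both with an adjusted p of 1. The Socs2 difference turned to 0.032 with position on the slide as a covariate and to 0.0077 with the share of probes detected as one, and it turned positive without some single arrays (up to 0.0062). Ghr, the GH receptor, was detected on 1 array and was not tested, and Igf1 was not analysed here because no probe was named for it. Of the 28 genes on the axis list 14 were measured, 0 rose and 0 fell within a time point, also adjusted over the list alone, and the lowest adjusted p of the list test was 0.58.

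**Figure D1:**
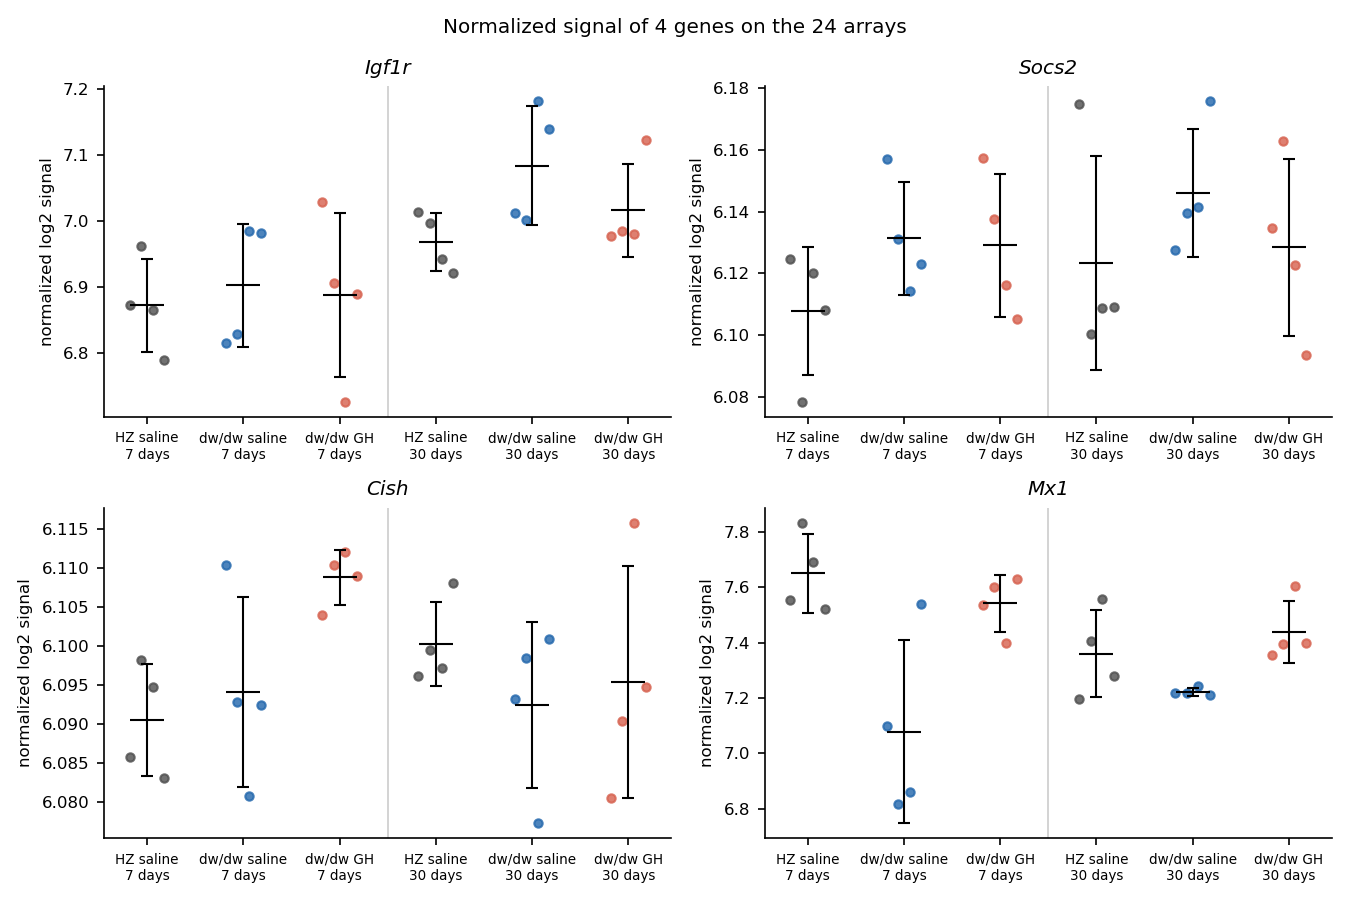
Normalized log2 signal (y axis) of Igf1r, Socs2, Cish and Mx1 on each array (points), by group (x axis), with the mean and SD of 4 animals as bars. At 7 days the dw/dw saline mean of Mx1 is 7.08 against 7.65 in HZ; each panel has its own y scale, which does not start at 0.

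The effect of GH deficiency at 7 days was read from dw/dw saline against HZ saline. All 12 measured markers of meninges and fibroblasts had lower values in dw/dw saline rats, with a median log2 difference of -0.17 (camera adjusted p = 1.4e-06). The call was lost with an estimated correlation, with an adjusted p of 0.79. Among its members, the collagen gene Col1a1 differed by -0.087 (SE 0.028), the proteoglycan gene Dcn by -0.46 (SE 0.18) and Lum by -0.27 (SE 0.12), with adjusted p of 0.57, 0.68 and 0.73. Choroid plexus markers, whose list includes Igf2, also had lower values, 4 of 5 negative with a median of -0.18, and so did red blood cell markers, 5 of 5 with -0.26, and neither list was called (camera adjusted p = 0.057 each). Igf2 and Igfbp2, which the meninges also express, differed by -0.85 (SE 0.37) and -0.74 (SE 0.39), with adjusted p of 0.71 and 0.79. The smallest p belonged to Mx1, an interferon-induced GTPase, at 7.08 ± 0.33 in dw/dw saline and 7.65 ± 0.14 in HZ (SD, n = 4), a difference of -0.57 (SE 0.12, adjusted p = 0.43). Mx1 was the 1 member of 8 measured on the MHC and interferon list that fell when adjusted over the list alone. Others near it were Pnma8b (0.22, SE 0.045, adjusted p = 0.43), the kinase gene Csnk1d (0.13, SE 0.032) and the G protein subunit gene Gnaq (0.14, SE 0.034) on the higher side. On the lower side were Calu (-0.19, SE 0.045), the electron transfer flavoprotein gene Etfa (-0.20, SE 0.056) and the ribosomal protein gene Rpl39 (-0.18, SE 0.049), these 5 with an adjusted p of 0.47. In the limma fit 0 probes passed after adjustment and 758 had an unadjusted p under 0.05, against 574 by chance. Without HZ replicate 1 the meninges list lost its call (median -0.090, adjusted p = 0.054), and without HZ replicate 3 its median was -0.28. With the series matrix values the median was -0.56. Calu passed without HZ replicate 2 (-0.24, adjusted p = 0.024). Without dw/dw saline replicate 4, whose Mx1 signal lay near the HZ values, the Mx1 difference was -0.73 with an adjusted p of 0.0018. Leaving out the array nearest to HZ enlarges the difference, so this p does not establish one.

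GH treatment for 7 days was compared with saline in dw/dw rats. Red blood cell markers had higher values under GH, with a median difference of 0.58 over 5 measured genes, 4 of them positive (camera adjusted p = 6.2e-05, and 0.26 with an estimated correlation). The haemoglobin chain genes Hba-a1, Hbb-b1 and Hbb differed by 0.65 (SE 0.19), 0.65 (SE 0.19) and 0.58 (SE 0.20). These 3 rose when adjusted over the list alone, and their adjusted p over all probes were 0.91, 0.91 and 1. The list score was 0.59 ± 0.13 under GH and 0.20 ± 0.06 under saline (SD, n = 4). Its exact permutation p was 0.029, the smallest that 4 against 4 allow, and 0.60 after adjustment over the 33 lists. Genes of cholesterol synthesis also had higher values, 14 of 15 positive with a median of 0.082 (camera adjusted p = 0.00072, and 0.38 with an estimated correlation). Dhcr7, which catalyses the last step of cholesterol synthesis, was at 8.43 ± 0.06 under GH and 8.25 ± 0.09 under saline (SD, n = 4) and was the 1 member that rose when adjusted over the list alone, by 0.18 (SE 0.045, adjusted p over all probes 0.88). Mvd, Hsd17b7 and Nsdhl, further enzymes of the pathway, had differences of 0.13, 0.090 and 0.082, each with an adjusted p of 1, and that of Hsd17b7 turned to -0.0031 with position on the slide as a covariate. Meninges and fibroblast markers were positive in 12 of 12, with a median of 0.11 (camera adjusted p = 0.00072, and 0.78 with an estimated correlation), Dcn at 0.34 (SE 0.18) and Lum at 0.20 (SE 0.12), each with an adjusted p of 1.

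Over all probes, 0 passed for GH against saline at 7 days in the limma fit, and 534 had an unadjusted p under 0.05, against 574 by chance. The smallest p belonged to the adaptor protein gene Sh3kbp1 (0.21, SE 0.043, adjusted p = 0.35), then the lipoxygenase gene Alox15 (0.14, SE 0.032, adjusted p = 0.58) and the transcription factor gene Rfx7 (0.28, SE 0.065, adjusted p = 0.64). Mx1 had a GH minus saline difference of 0.46 (SE 0.12, adjusted p = 0.88) and rose when adjusted over the interferon list alone. On the lower side were Srek1ip1 (-0.20, SE 0.046), Tti1, part of a chaperone complex for kinases of the mTOR family (-0.22, SE 0.051), and Klk8, a secreted serine protease of the hippocampus (-0.30, SE 0.078), with adjusted p of 0.58, 0.64 and 0.88. Without dw/dw saline replicate 4 the Mx1 difference was 0.62 (adjusted p = 0.018) and the cholesterol list lost its call (median 0.050, adjusted p = 0.057). The Mx1 differences for deficiency and for GH share the dw/dw saline arrays, so neither backs the other. Without dw/dw GH replicate 4 the meninges list lost its call (median 0.043, adjusted p = 0.13) and the cholesterol median was 0.048, and without dw/dw GH replicate 2 the meninges median was 0.16. With the series matrix values it was 0.43.

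GH-treated dw/dw rats were compared with HZ saline controls at 7 days. Cholesterol synthesis genes had a median difference of 0.079, with 13 of 15 positive (camera adjusted p = 0.0023, and 0.82 with an estimated correlation). Mvd, a decarboxylase of the mevalonate pathway, rose when adjusted over the list alone, by 0.19 (SE 0.055, adjusted p over all probes 0.81). Hsd17b7, Srebf1 and Dhcr7 had differences of 0.089, 0.16 and 0.076, each with an adjusted p of 1. Macf1, a linker of microtubules and actin, had the smallest p, with 0.24 (SE 0.044, adjusted p = 0.41), followed by the palmitoyltransferase gene Zdhhc3 (0.12, SE 0.025, adjusted p = 0.66). Slc25a29, Dstyk and Ppip5k1, an inositol pyrophosphate kinase gene, had 0.18, 0.15 and 0.17, each with an adjusted p of 0.79. The acetyltransferase gene Naa20, Mok and Fxyd7, a regulator of the sodium pump, had -0.22, -0.19 and -0.23, again at 0.79. In the limma fit 0 probes passed and 466 had an unadjusted p under 0.05. The cholesterol call was lost without dw/dw GH replicate 2 (median 0.069, adjusted p = 0.064), dw/dw GH replicate 4 (0.047, 0.13) and HZ replicate 2 (0.030, 0.051), and its median was 0.19 with median scaling. Macf1 passed without HZ replicate 1 (0.28, adjusted p = 0.021) and Slc25a29 without dw/dw GH replicate 4 (0.24, adjusted p = 0.013).

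After 30 days, dw/dw saline rats had slightly lower values of oxidative phosphorylation genes than HZ rats, with 28 of 38 measured members negative and a median difference of -0.027 (camera adjusted p = 0.045, and 0.64 with an estimated correlation). The list score was -0.02 ± 0.00 in dw/dw saline and 0.01 ± 0.02 in HZ (SD, n = 4; exact permutation p = 0.029, 0.58 after adjustment). Sdhb, a subunit of complex II, differed by -0.13 (SE 0.050, adjusted p = 0.63), Ndufv1 of complex I by -0.13 (SE 0.056, adjusted p = 0.67) and Cycs, cytochrome c, by -0.20 (SE 0.10, adjusted p = 0.69), and 0 members fell when adjusted over the list alone. With position on the slide as a covariate the Sdhb difference turned to 0.051. Zcchc9, a zinc finger protein gene, had the smallest p, at 6.54 ± 0.08 in dw/dw saline and 6.75 ± 0.03 in HZ (SD, n = 4), a difference of -0.21 (SE 0.037, adjusted p = 0.19). It was followed by Mcee, an epimerase of propionate breakdown (-0.27, SE 0.059, adjusted p = 0.27), and Kcnb2, a voltage-gated potassium channel gene (-0.050, SE 0.011, adjusted p = 0.29). Ppip5k1 had 0.19 (SE 0.042, adjusted p = 0.29), and Dstyk, Vapb, the tRNA synthetase gene Cars1 and the telomere maintenance gene Ctc1 had 0.15, 0.18, 0.11 and 0.19, each with an adjusted p of 0.45. In the limma fit 0 probes passed and 820 had an unadjusted p under 0.05, against 574 by chance. The oxidative phosphorylation call was lost without dw/dw saline replicates 1 or 4 or HZ replicates 2, 3 or 4 of this time point (adjusted p up to 0.38, medians between -0.041 and -0.022). It was also lost without dw/dw GH replicates 1 or 4 or HZ replicates 1 or 4 of the 7-day arrays (adjusted p up to 0.054), and with the series matrix values (adjusted p = 0.15). Its median was -0.042 without HZ replicate 1 of this time point and -0.072 with median scaling. Kcnb2 lay close to background, at 6.11 ± 0.01 in dw/dw saline and 6.16 ± 0.02 in HZ (SD, n = 4). It passed with the series matrix values (-0.74, adjusted p = 0.043), which were used without an offset, so the size of this difference is uncertain. Zcchc9 passed with array weights (-0.23, adjusted p = 0.022) and without dw/dw GH replicate 1 of the 7-day arrays (-0.21, adjusted p = 0.018). Without dw/dw saline replicate 1, 5 probes passed: Rps13 (-0.41, adjusted p = 0.017), Mcee (-0.33, 0.045), Zcchc9 (-0.23, 0.045) and 2 unnamed ones, Rps13 being named here after its values were seen.

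GH treatment for 30 days was again set against saline in dw/dw rats. The red blood cell list was the 1 list called, with 5 of 5 measured genes positive and a median difference of 0.47 (camera adjusted p = 0.00025, and 0.38 with an estimated correlation). Hba-a1, Hbb-b1 and Hbb had differences of 0.56 (SE 0.19), 0.53 (SE 0.19) and 0.47 (SE 0.20). These 3 rose when adjusted over the list alone, and each had an adjusted p of 1 over all probes. Hba-a1 was at 11.53 ± 0.17 under GH and 10.96 ± 0.44 under saline (SD, n = 4). Named genes with the smallest p were Mrpl34 of the mitochondrial ribosome (0.17, SE 0.040), the replication origin gene Orc5 (0.22, SE 0.056), Chchd3 of the mitochondrial inner membrane (0.19, SE 0.049). On the lower side were Xbp1, a transcription factor of the unfolded protein response (-0.18, SE 0.045), Dstyk (-0.14, SE 0.037) and Cxxc5 (-0.24, SE 0.069), and all 6 had an adjusted p of 1. Xbp1 was the 1 member of the heat shock and unfolded protein list that fell when adjusted over the list alone. In the limma fit 0 probes passed and 386 had an unadjusted p under 0.05, fewer than the 574 by chance. Without dw/dw saline replicate 3, the array with the highest haemoglobin signal of its group, the red blood cell median was 0.71.

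Between GH-treated dw/dw rats and HZ controls at 30 days, 3 lists had higher values in the GH group. Meninges and fibroblast markers were positive in 11 of 12, with a median difference of 0.11 (camera adjusted p = 0.0023), oligodendrocyte and myelin genes in 12 of 13, with 0.045 (adjusted p = 0.046), and red blood cell genes in 5 of 5, with 0.40 (adjusted p = 0.013). With an estimated correlation the adjusted p was 0.83 for each of the 3. Ptgds, a prostaglandin D synthase gene of the meninges, was at 12.75 ± 0.48 in dw/dw GH and 12.04 ± 0.22 in HZ (SD, n = 4), a difference of 0.71 (SE 0.30, adjusted p = 0.89). Igfbp2 and Col1a2 had 0.81 (SE 0.39) and 0.79 (SE 0.39), and Hbb-b1 had 0.42 (SE 0.19), each with an adjusted p of 0.89. The myelin genes Mag and Mbp had 0.033 (SE 0.019) and 0.17 (SE 0.13), with adjusted p of 0.91 and 0.92. Outside the lists, Tm4sf1 had 0.18 (SE 0.034, adjusted p = 0.25), the complexin gene Cplx1 had 0.096 (SE 0.026, adjusted p = 0.79), Zcchc9 had -0.19 (SE 0.037, adjusted p = 0.25) and Mtx1, a mitochondrial import protein gene, had -0.20 (SE 0.040, adjusted p = 0.29). The translation initiation factor gene Eif2s1 had -0.28 (SE 0.071, adjusted p = 0.67). In the limma fit 0 probes passed and 630 had an unadjusted p under 0.05. The meninges call was lost without dw/dw GH replicate 4 (median 0.050, adjusted p = 0.31) and HZ replicate 2 (0.093, 0.063). The red blood cell call was lost without dw/dw GH replicates 1 or 4 or HZ replicates 1 or 2 (adjusted p between 0.071 and 0.084, medians 0.34 to 0.40). The oligodendrocyte call was lost without dw/dw GH replicates 1 (median 0.035, adjusted p = 0.57) or 4 (0.040, 0.22) and HZ replicates 1, 2 or 3 (adjusted p up to 0.096, median 0.074 without replicate 2). It was also lost without 4 arrays of other groups, namely dw/dw saline replicates 1 and 3 at 30 days and dw/dw GH replicate 1 and HZ replicate 2 at 7 days (adjusted p up to 0.054), and with median scaling (0.024, adjusted p = 0.083). Without dw/dw GH replicate 2 its median was 0.090, and with the series matrix values it was 0.091, and that of the meninges list 0.75.

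**Figure D2:**
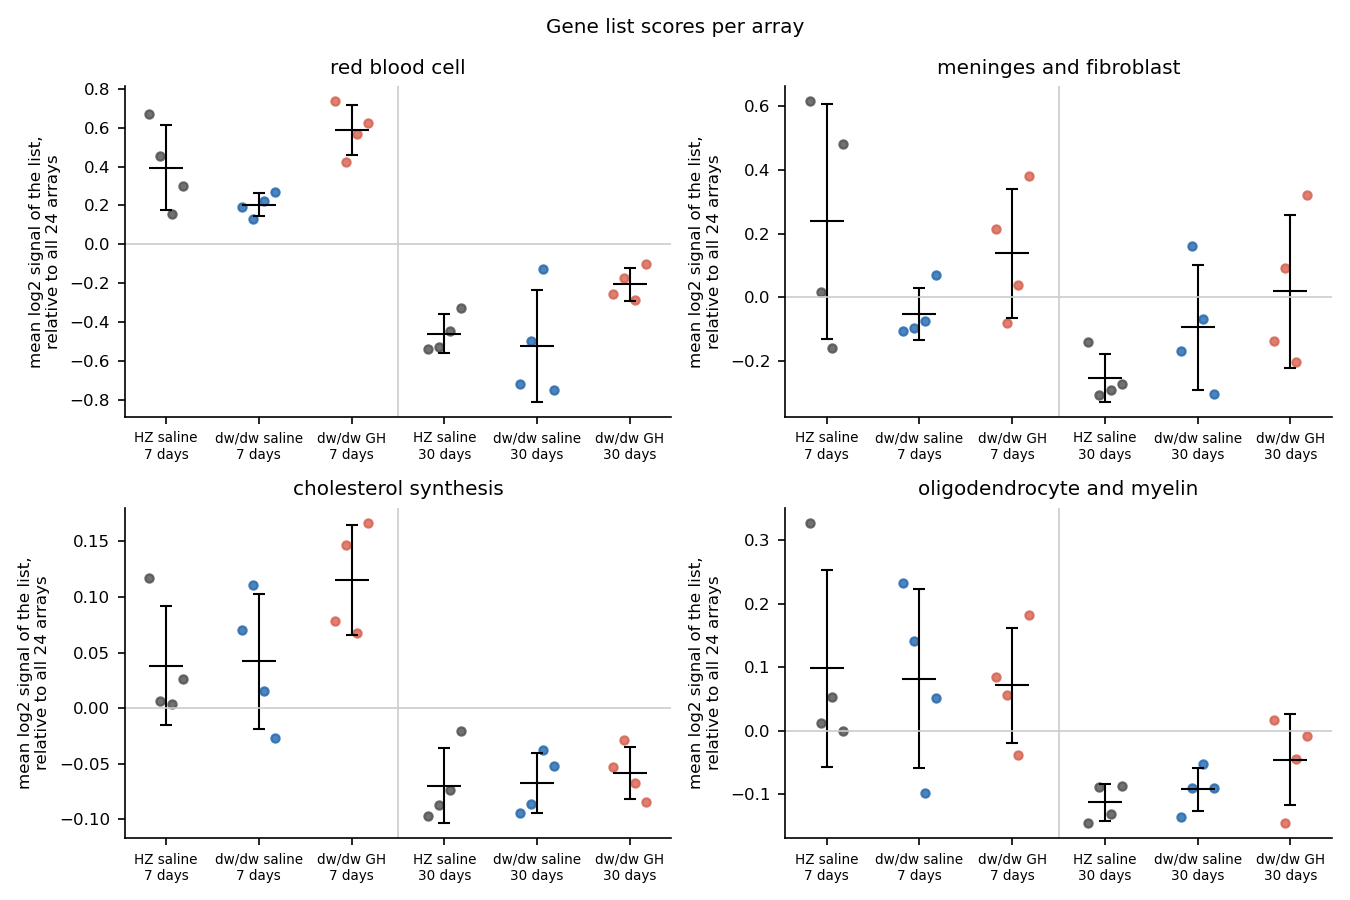
Score of 4 gene lists on each array (points; y axis, mean log2 signal of the list relative to all 24 arrays), by group (x axis), with the mean and SD of 4 animals as bars. The red blood cell score is 0.59 under GH and 0.20 under saline in dw/dw rats at 7 days, and all 4 lists have lower scores in HZ rats at 30 days than at 7 days.

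Whether the effects differed between the time points was tested with interaction contrasts. For the GH effect 0 probes passed in the limma fit and 592 had an unadjusted p under 0.05, and for the deficiency effect 0 passed and 459 did, against 574 by chance. The smallest p for the GH effect belonged to Rfx7 (-0.44, SE 0.092), Tti1 (0.34, SE 0.072), Chchd3 (0.32, SE 0.070), Mrpl34 (0.26, SE 0.057) and Dstyk (-0.24, SE 0.052), each with an adjusted p of 0.46. With the share of probes detected as a covariate, Tti1 (0.42, limma adjusted p = 0.043) and Arl6ip6 (-0.27, 0.0078) passed, Arl6ip6 being named here after its values were seen. For the deficiency effect, Npr2, a natriuretic peptide receptor gene (0.24, SE 0.055), Lyve1, a marker of lymphatic vessels and border macrophages (0.075, SE 0.018), and the neuronal transcription factor gene Neurod1 (-0.32, SE 0.090) were among those with the smallest p, each with an adjusted p of 1. The meninges and fibroblast list, tested in these contrasts after the data were seen, had a positive change of the deficiency effect in 12 of 12 members, with a median of 0.24 (camera adjusted p = 4e-07, and 0.69 with an estimated correlation), Dcn at 0.64 (SE 0.25) and Col1a2 at 1.13 (SE 0.55). With the series matrix values the median was 0.92. No other list was called for either change, and the lowest adjusted p was 0.17 for the deficiency effect and 0.47 for the GH effect.

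Whether GH moved genes back towards control levels was examined by correlating the deficiency difference with the GH difference across the 11487 probes. Both differences contain the dw/dw saline arrays, and probes are not independent replicates. Pearson's r was -0.59 at 7 days, where unchanged groups sharing those arrays gave a mean of -0.49 (simulated range -0.83 to -0.037), and the covariance was -0.0025 against a simulated -0.0021. At 30 days r was -0.44 against a simulated -0.49 (-0.86 to 0.097), with a covariance of -0.0017 against -0.0018. With the dw/dw saline arrays split between the comparisons, r was -0.10 (simulated -0.43 to 0.42) at 7 days and -0.050 (-0.54 to 0.46) at 30 days, and neither value left its simulated range. Median scaling turned both split values positive, to 0.13 and 0.067. The deficiency differences at 7 and 30 days, which share no array, had r = 0.33 (simulated -0.47 to 0.46), those of GH against HZ 0.29 (-0.45 to 0.45) and those of GH against saline -0.10 (-0.47 to 0.46). In the same order these were 0.18, -0.020 and -0.14 with median scaling, and 0.10, 0.12 and -0.11 with the series matrix values. No probe was called at both times in any of these comparisons. At an unadjusted p under 0.05, 48 probes were higher and 67 lower in dw/dw saline than HZ rats at both times, where independent lists would share 15.1 and 11.9. For GH against saline the shared counts were 6 and 5 against 3.61 and 5.41, and for GH against HZ 9 and 29 against 6.18 and 6.25.

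The mean of the 4 dw/dw groups against the mean of the 2 HZ groups asked which genes differ with genotype on average over treatments and time points. It does not require a difference in each group. Ppip5k1 (0.14, SE 0.026), Mtx1 (-0.13, SE 0.024), Zcchc9 (-0.12, SE 0.023) and Rps13, a protein gene of the small ribosomal subunit (-0.27, SE 0.052), came closest, each with a limma adjusted p of 0.051. Macf1 (0.13, SE 0.027), Pnma8b (0.13, SE 0.028), the ubiquitin-conjugating enzyme gene Ube2q1 (-0.13, SE 0.029) and Acsl4, an acyl-CoA synthetase gene for arachidonate (-0.16, SE 0.037), followed with adjusted p of 0.069, 0.11, 0.13 and 0.13. Rps13 was at 6.80 ± 0.09, 6.89 ± 0.06 and 7.09 ± 0.05 in dw/dw saline, dw/dw GH and HZ rats at 7 days, and at 6.99 ± 0.24, 6.99 ± 0.11 and 7.28 ± 0.10 at 30 days (SD, n = 4). Zcchc9 differed mainly at 30 days, with means of 6.45, 6.51 and 6.53 in the same order at 7 days and 6.54, 6.55 and 6.75 at 30 days. Ppip5k1 at 30 days was at 8.35 ± 0.08 in dw/dw GH and 8.30 ± 0.07 in HZ rats (SD, n = 4). No probe passed, and 1102 had an unadjusted p under 0.05, 531 higher and 571 lower, against 574 by chance. The count past the threshold was 16 with no background correction, 15 with a trended and robust eBayes, 12 with the stricter filter and 34 without dw/dw saline replicate 1 at 30 days, whose Rps13 and Acsl4 signals lay far from those of its group. Probes also passed with the replicate number as a block and without the arrays numbered 1 at 30 days, as given further below. No list was called (lowest camera adjusted p = 0.31). With position on the slide as a covariate the count was 0, and 681 probes had an unadjusted p under 0.05. Because position follows group on both slides, that fit estimates the genotype difference with less precision. The lower number of probes thus cannot tell genotype from position.

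Maturation from 42 to 65 days was read in HZ rats, with slide and age inseparable. Here 264 probes passed, 120 higher and 144 lower at 30 days, and 1985 had an unadjusted p under 0.05. The change in HZ rats had the same sign in dw/dw saline rats for 253 of the 264 and in dw/dw GH rats for 255, with median sizes of 0.23 in HZ, 0.14 in dw/dw saline and 0.13 in dw/dw GH rats. The largest rise was that of Qdpr, which regenerates the cofactor tetrahydrobiopterin, from 8.82 ± 0.13 to 9.66 ± 0.11 (SD, n = 4), 1.79-fold (SE 0.068 log2, adjusted p = 1.3e-06). In dw/dw rats it was 8.80 ± 0.15 and 9.65 ± 0.08 under saline and 8.79 ± 0.03 and 9.70 ± 0.04 under GH (SD, n = 4). The potassium channel gene Kcnd3 rose 1.46-fold, the phospholipid enzyme gene Cds1 1.39-fold, the prohormone convertase chaperone gene Scg5 1.37-fold and the monoamine oxidase gene Maob 1.36-fold, with adjusted p of 0.033, 0.0012, 0.0045 and 0.044. Ik, the RNA-binding protein gene Ssb, Ptma, the protein kinase A subunit gene Prkaca and the MHC class I gene RT1-A1 rose by 0.43, 0.40, 0.37, 0.37 and 0.36, with adjusted p between 0.030 and 0.049.

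Among the genes that fell with age in HZ rats, the haemoglobin genes Hbb-b1, Hbb and Hba-a1 fell by 1.51 (SE 0.19), 1.39 (SE 0.20) and 1.31 (SE 0.19), with adjusted p of 0.00037, 0.0012 and 0.0012. The fetal growth factor gene Igf2 and the IGF-binding protein gene Igfbp2 were 2.78-fold (SE 0.37 log2) and 2.83-fold (SE 0.39 log2) lower, with adjusted p of 0.041 and 0.046. Igf2 was at 11.18 ± 0.88 at 7 days and 9.71 ± 0.18 at 30 days (SD, n = 4). At 7 days it was highest on HZ replicates 1 and 4 (12.1 and 11.8 against 10.5 and 10.4), as was Igfbp2 (9.87 and 9.50 against 8.22 and 7.77). The meninges and fibroblast score was also highest on these arrays (0.617 and 0.483 against 0.016 and -0.159). Both genes lost the call when either array was left out, but also without any 1 of the HZ arrays at 30 days. Igfbp2 also lost it without several of the dw/dw arrays in turn and with an offset of 50. The loss is therefore not particular to HZ replicates 1 and 4 at 7 days. Whether meninges carried along with the tissue gave these falls was not tested. The lipase gene Pnlip fell by 0.93, Rarres2, which encodes the adipokine chemerin, by 0.67, the myelin gene Mobp by 0.63, the dynein light chain gene Dynlt1 by 0.60 and Clec2l by 0.42, with adjusted p between 1.1e-05 and 0.041. By lists, red blood cell genes had a median of -1.31 (5 of 5 negative, camera adjusted p = 1.6e-07) and oligodendrocyte precursor genes one of -0.15 (6 of 6, adjusted p = 0.001), both with an adjusted p of 0.037 with an estimated correlation. Pdgfra, the receptor that marks these precursors, fell by 0.35 (SE 0.079, adjusted p = 0.033). Meninges and fibroblast genes had a median of -0.27 (12 of 12 negative, adjusted p = 7.3e-07), oligodendrocyte and myelin genes -0.18 (12 of 13, adjusted p = 7.8e-05) and cholesterol synthesis genes -0.13 (10 of 15, adjusted p = 0.0018), each with an adjusted p of 0.40 with an estimated correlation. Adjusted over the list alone, 6 of 12 meninges genes, 5 of 13 myelin genes, 4 of 6 precursor genes and 4 of 5 red blood cell genes fell, and of 15 cholesterol genes 6 fell and 1 rose. Over all probes, 3 cholesterol genes fell, Dhcr7 by 0.30 (SE 0.045, adjusted p = 0.0023), Fdft1 by 0.28 and Mvd by 0.24, and Col1a2 fell by 1.57 (SE 0.39, adjusted p = 0.041).

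The age count changed with the processing. It was 9 with median scaling (4 higher, 5 lower) and 1954 with the authors' series matrix values (50 higher, 1904 lower), where the median of all probes differed by -0.13. It was 93 with no filter on detection and 142 with array weights. Qdpr, Cds1, Hbb-b1, Hbb and Hba-a1 passed under every setting run, including each array left out, while 15 of the 20 genes named here by the size of their change lost the call with median scaling, as did the cholesterol list (median -0.045, adjusted p = 0.083). Of these 20 genes, 11 lost it with the share of probes detected as a covariate and 12 without the arrays numbered 1 at 30 days. The count was 41 without HZ replicate 1, 70 without HZ replicate 3 and 61 without HZ replicate 4 at 30 days, and 53 without HZ replicate 1 and 66 without HZ replicate 2 at 7 days. Without HZ replicate 1 at 7 days the median of the oligodendrocyte and myelin list was -0.11, as with median scaling. With the series matrix values the medians were -0.26 for cholesterol synthesis, -0.34 for oligodendrocyte and myelin, -0.42 for oligodendrocyte precursor and -1.22 for meninges and fibroblast genes.

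**Figure D3:**
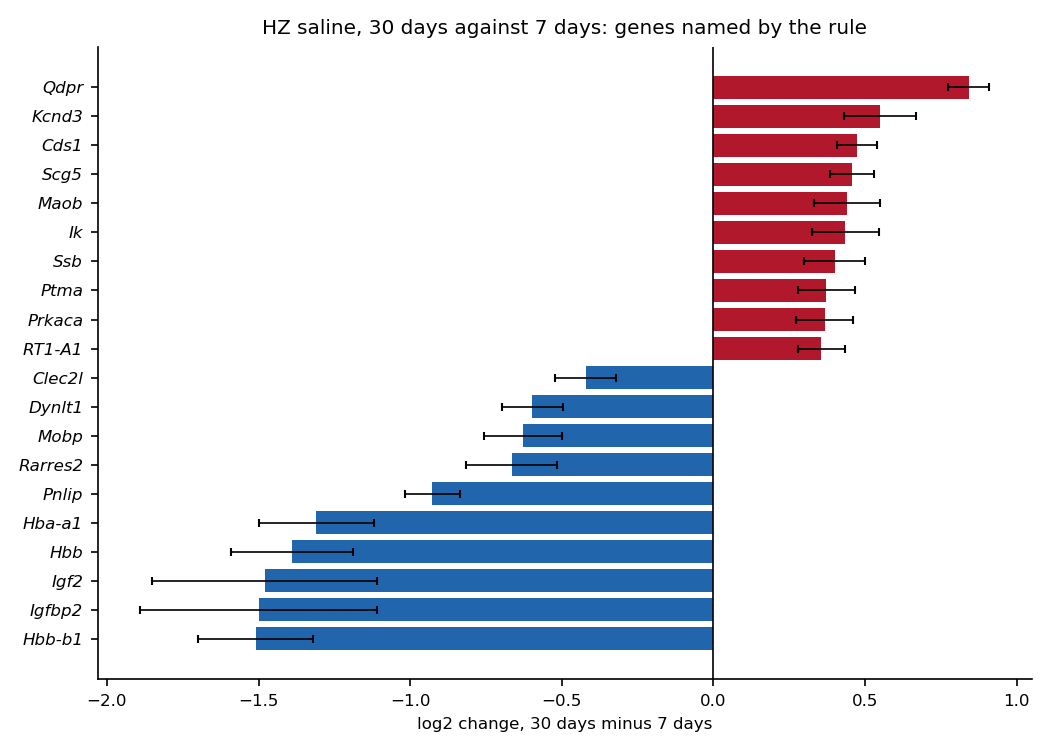
Log2 change (x axis) in HZ rats from 7 to 30 days of saline, that is from 42 to 65 days of age, for the genes with the largest rises (red) and falls (blue) among probes past the threshold whose values did not overlap between the groups. Bars start at 0 and error bars are the SE from the limma fit; Qdpr leads the rises with 0.84 and Hbb-b1 the falls with -1.51.

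Of the 33 lists, 28 were not called in any comparison within a time point, with camera adjusted p of 0.051 or more. The lowest adjusted p was 0.051 for MHC and interferon response, 0.057 for choroid plexus, 0.073 for endothelial cell, 0.084 for heat shock and unfolded protein response, 0.11 for neurogenesis and proliferation, for microglia and for striatum. It was 0.12 for thyroid hormone-responsive genes and 0.16 for ribosomal proteins. It was 0.23 for glucose uptake and glycolysis, 0.28 for activity-regulated immediate early genes, 0.30 for synaptic vesicle and postsynaptic density and for angiogenesis, 0.34 for oligodendrocyte precursor, 0.46 for PI3K, Akt and mTOR signalling, 0.54 for CA pyramidal neuron and 0.56 for mural cell. Glutamate receptors, glucocorticoid-responsive genes, dentate granule neuron and GABAergic interneuron each had 0.58, as the GH and IGF axis did. GABA synthesis, transport and receptors, circadian clock and neocortex each had 0.62, and antioxidant defence, astrocyte and thalamus each had 0.65. With the estimated correlation, and with fry, 0 of the 198 list tests within a time point were called.

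**Figure D4:**
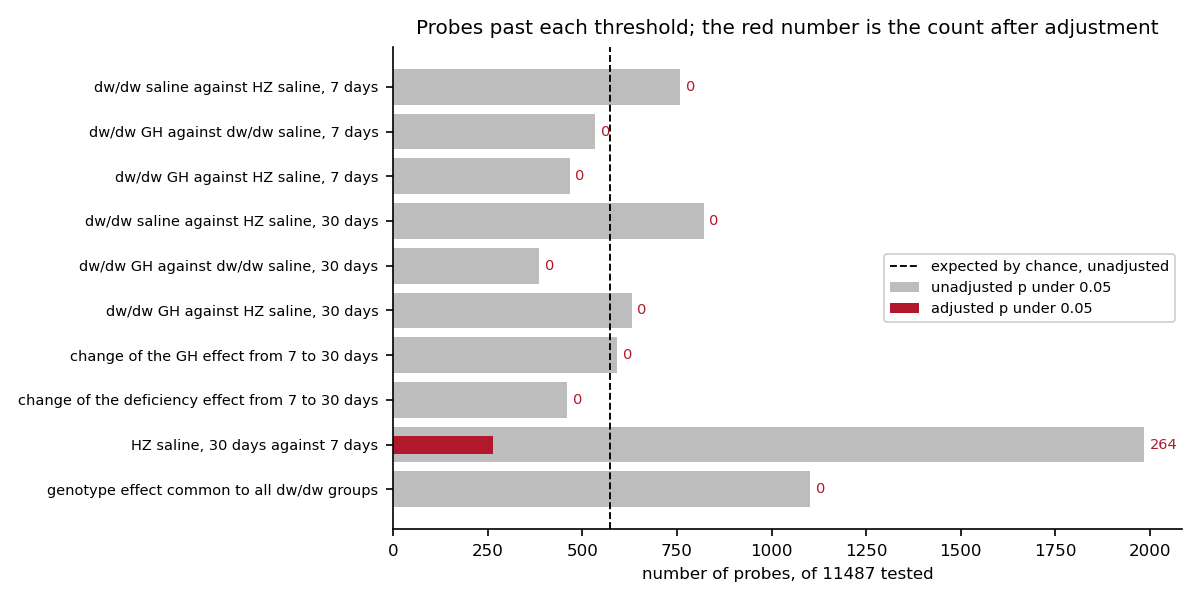
Number of probes (x axis) with an unadjusted p under 0.05 (grey bars) and an adjusted p under 0.05 (red bars, number printed in red) in each of the 10 comparisons (y axis). The dashed line marks the 574 probes that chance gives; HZ rats at 30 against 7 days stand at 1985 and 264, and the other comparisons at 386 to 1102 and 0.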

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

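The tests of meningeal tissue and of blood left in the tissue, the list test of the change between time points and the list tests without each array were chosen only after the results were seen. In 22 of 456 groups of 4 arrays, 1 array lay far from the other 3, its gap to the nearest of them being a large share of the group's range (given below). Chance flags about 1 in 20 groups, so the number of flags is about what chance gives.

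At 7 days, in dw/dw saline rats, replicate 2 lay above the others for Herc3 (8.19 against 8.11 to 8.12, share 0.851). In dw/dw GH rats, replicate 4 lay below the others for Chchd3 (8.93 against 9.12 to 9.15, share 0.87) and Tmem106c (8.33 against 8.44 to 8.47, share 0.84) and above them for Col1a1 (6.21 against 6.13 to 6.14, share 0.833). Replicate 2 of that group lay below the others for Igf2r (9.12 against 9.34 to 9.36, share 0.953) and Macf1 (share 0.873). In HZ rats, replicate 1 lay above the others for the oligodendrocyte and myelin score (0.33 against 0.00 to 0.053, share 0.838) and below them for Sidt1 (6.15 against 6.20 to 6.21, share 0.841). Replicate 2 lay above them for Dstyk (9.37 against 9.30 to 9.31, share 0.839) and replicate 3 below them for Dcn (8.60 against 8.98 to 9.05, share 0.85).

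At 30 days, dw/dw saline replicate 1 lay above the others for Acsl4 (6.53 against 6.29, share 0.988), Rps13 (7.35 against 6.82 to 6.90, share 0.851) and Igfbp3 (6.38 against 6.30 to 6.31, share 0.841), and below them for Stat5a (6.09 against 6.11, share 0.869). In dw/dw GH rats, replicate 1 lay above the others for Acsl4 (6.44 against 6.31 to 6.33, share 0.838) and replicate 4 for Igf1r (7.12 against 6.98, share 0.946). In HZ rats, replicate 1 lay above the others for Igfbp2 (7.76 against 7.14 to 7.24, share 0.838) and Socs2 (6.17 against 6.10 to 6.11, share 0.884) and below them for Qdpr (9.49 against 9.69 to 9.73, share 0.845). Above the others of this group were also replicate 2 for Ctc1 (7.20 against 7.02 to 7.03, share 0.939), replicate 3 for Igfbp3 (6.43 against 6.34 to 6.35, share 0.897) and replicate 4 for Ahsp (6.08 against 6.04, share 0.856).

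The meninges and fibroblast list was singled out because its deficiency effect differed between the time points, with a median change of 0.242 in the interaction contrast (camera adjusted p = 4e-07 with the preset correlation, 0.69 with an estimated one). Varying amounts of meninges carried along with the dissected hippocampus may underlie this: within groups the residuals of these markers had a mean correlation of 0.75, so that they moved together from array to array. The residual means of choroid plexus and meninges markers had r = 0.70 over the 24 arrays (permutation p = 0.031, also 0.031 adjusted over both relations tested). Spearman's rho was 0.63, and r was 0.60 without the 2 farthest arrays and 0.83 and 0.44 within the slides. Igf2, which the meninges also express, is among the 5 measured choroid plexus markers. Part of this correlation may therefore come from Igf2, and it was not recomputed without that gene. The exact permutation p of the meninges and fibroblast score at 7 days was 0.26. A single array does not account for the change between time points, since its call with the preset correlation held without any 1 array (median 0.17 to 0.318, highest adjusted p = 0.0011), whereas 2 of the 8 arrays at 7 days each ended the call at 7 days or moved its median by over 1.5 times. Meningeal tissue stays open for both, a single array for the 7-day difference alone, and a response of meningeal cells to GH deficiency was not tested apart from them.

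The haemoglobin genes Hba-a1, Hbb-b1 and Hbb had higher values under GH than under saline at both time points, where the red blood cell list was called. Only these genes rose when adjusted over that list alone, so the result rests on haemoglobin. With an estimated correlation neither list call held (camera adjusted p = 0.26 at 7 days and 0.38 at 30 days). Blood left in the tissue could give this, and within groups the residuals of the markers had a mean correlation of 0.41. With the preset correlation, a single array does not account for the result at 7 days, where 0 of the 8 arrays ended the call or moved the median by over 1.5 times (highest adjusted p = 0.01). At 30 days 1 of the 8 moved the median that far (highest adjusted p = 0.028). The residual means of red blood cell and endothelial markers had r = 0.49 over the 24 arrays (permutation p = 0.016, 0.031 adjusted over both relations tested; Spearman's rho 0.46; 0.41 without the 2 farthest arrays; 0.59 and 0.41 within the slides), so more blood vessels also stay possible. The endothelial list itself was not called within a time point (lowest camera adjusted p = 0.073). In dw/dw rats at 7 days its score lay between 0.024 and 0.086 under GH and between -0.11 and 0.045 under saline. At 30 days the ranges were -0.095 to 0.063 and -0.069 to 0.016. The median differences of this list within a time point were small, between -0.0356 and 0.0305.

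The probes that differed between HZ rats at 30 and at 7 days may owe part of their difference to the slides, since all arrays of a time point shared 1 slide. A slide effect should appear in dw/dw arrays at the same size, and the median was 0.139 over both dw/dw treatments (0.143 under saline, 0.129 under GH) against 0.23 in HZ rats, where the probes were selected. Selecting probes in HZ rats favours larger values there, to an extent that was not tested, so age and slide stay inseparable.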

How the results depend on the processing

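The share of probes detected as a covariate, the arrays numbered 1 at 30 days left out together and the list tests without each array were added after the results were seen. Signal over background limits what could be measured: Cish and Socs2 lay near background, where the offset compresses log2 differences. Fitting each time point alone or with an offset of 50 moved no count across 0 or by over 1.5 times. The change of either effect, GH against saline at 30 days and GH against HZ at 30 days kept a count of 0 in every leave-one-out fit. Unless stated, the cause was not tested.

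For HZ rats at 30 against 7 days the count of 264 was 9 with median scaling, 142 with array weights, 93 with no filter on detection, 164 with the detected share as covariate, 48 without the arrays numbered 1 at 30 days and 1954 with the series matrix values. The last set carries a difference between the slides, its column medians centring on 9.77 at 7 days and 8.61 at 30 days. Leaving out 1 array gave 41 (HZ 30 days replicate 1) to 299 (HZ 7 days replicate 4). The cause was not tested.

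For the genotype effect the count of 0 was 16 with no background correction, 12 with the strict filter, 15 with trend and robust eBayes and 25 without the arrays numbered 1 at 30 days. Leaving out 1 array gave 0 to 34 (without dw/dw saline 30 days replicate 1). The cause was not tested.

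For dw/dw saline against HZ at 30 days the count of 0 was 1 with array weights (Zcchc9), 1 with the series matrix values (Kcnb2) and 1 without the arrays numbered 1 (Rps13), and leaving out 1 array gave 0 to 5. At 7 days it was 0 to 1 for dw/dw saline against HZ (Mx1 or Calu), 0 to 1 for GH against saline (Mx1) and 0 to 1 for GH against HZ (Slc25a29 or Macf1). With the detected share as covariate, 1 probe passed for GH against saline at 7 days, 1 at 30 days (Arl6ip6) and 2 for the change of the GH effect (Tti1 and Arl6ip6). The cause was not tested.

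With the replicate number as a block, 1 unnamed probe passed for dw/dw saline against HZ at 7 days and 11 for the genotype effect. The labels do not say that a number marks a pair. Of 24 arrays, 10 had their best correlation with an array of their own number, and the mean residual correlations of the numbers were -0.07, 0.18, 0.029 and 0.11 at 7 days and 0.46, 0.063, -0.029 and 0.072 at 30 days, so the numbers were not treated as pairs.

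Of the 198 list tests within a time point 10 were called, 0 with an estimated correlation, 17 with median scaling (9 of the 10 among them), and 6 (without HZ 30 days replicate 2) to 16 (without HZ 7 days replicate 3) with 1 array left out. With median scaling the split correlations of deficiency against GH were 0.128 at 7 days and 0.0669 at 30 days, the correlation between time points for GH against HZ was -0.0203, and Igf1r had 0.0104 for GH against saline at 7 days. The cause was not tested.

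With position on the slide as covariate, Socs2 had -0.0444 for dw/dw saline against HZ, 0.0317 for GH against saline and -0.0127 for GH against HZ at 7 days, then -0.0451, 0.0163 and -0.0288 at 30 days, and -0.0327 for the genotype effect. Hsd17b7 had -0.00313 for GH against saline at 7 days, Igfbp3 0.00371 and Sdhb 0.0515 for dw/dw saline against HZ at 30 days, and Olig1 -0.0317 for GH against HZ at 30 days. Position follows group on both slides, so group differences are imprecise in this fit and a turned sign decides nothing. With the detected share as covariate, Socs2 had 0.00772 for GH against saline at 7 days and 0.0116 for the change of the deficiency effect, and Igf1r -0.0099 for GH against HZ at 7 days and 0.024 for the change of the GH effect. Socs2 had 0.00946 for the change of the deficiency effect with array weights, and without the arrays numbered 1 at 30 days 0.0225 for that change and -0.00164 for HZ at 30 against 7 days. The cause was not tested.

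With 1 array left out, these differences changed sign. Cish had -0.00181 to 0.00808 for dw/dw saline against HZ at 7 days, -0.00389 to 0.00793 for GH against saline and -0.0116 to 0.00013 for GH against HZ at 30 days. Socs2 had -0.0116 to 0.0062 for GH against saline at 7 days, -0.0063 to 0.0223 for GH against HZ at 30 days, -0.00169 to 0.0232 for HZ at 30 against 7 days and -0.0106 to 0.0164 for the change of the deficiency effect. Igf1r had -0.0627 to 0.0388 for GH against saline and -0.0322 to 0.0691 for GH against HZ at 7 days. The cause was not tested.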

Other observations

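Some genes differed between dw/dw saline and HZ rats in the same direction at both time points, each at an unadjusted p under 0.05. These genes were chosen after their values were seen, and the tests of a genotype difference at both times, of chromosome 6 and of the first principal component were likewise chosen only after the result was seen. Of 115 such probes 48 were higher and 67 lower in dw/dw saline rats, 63 of them named. Log2 differences at 7 and 30 days were -0.29 and -0.30 for Rps13 and -0.29 and -0.44 for Mrpl17, protein genes of the cytosolic and the mitochondrial ribosome, -0.26 and -0.24 for Scg2, which encodes a secretory granule protein, and -0.23 and -0.19 for Ywhag, a 14-3-3 protein gene. They were -0.12 and -0.15 for Mtx1, -0.13 and -0.21 for Acsl4, -0.15 and -0.11 for Ube2q1, 0.13 and 0.19 for Ppip5k1, 0.16 and 0.11 for Macf1 and 0.22 and 0.11 for Pnma8b.

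A genotype difference present at both time points was tested by splitting the arrays within each time point. The real grouping gave 115 probes of the same sign, 19 had opposite signs, the median of the other splits was 12 and the highest 244. As many came up in 3 of 100 splits, the real one included, but this test counts the same overlap that prompted it, and the split of the genotype effect given below does not exclude chance, so a difference at both times is not established. Position on the slide, which follows genotype on both slides, stays open as an explanation. Variants linked to the dwarf locus were tested by chromosome, on the assumption, stated in no source used here, that it lies on chromosome 6. There 44 of 343 probes had an unadjusted p under 0.05 for the genotype effect (12.8%, against 8.38% elsewhere; odds ratio 1.61, confidence interval 1.13 to 2.24, Fisher exact test p = 0.0057, and 0.12 after adjustment over 21 chromosomes). Only 688 of the 1102 probes (62.4%) had a chromosome and entered the test. That share is below the minimum the plan set for running it, so the test decides nothing and the explanation stays open.

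That GH returns genes towards the control level predicts a negative correlation between the deficiency and GH differences when no array is shared. With split dw/dw saline arrays it was -0.101 at 7 days and -0.05 at 30 days, against a simulated mean of -0.0091, and both lay within the simulated ranges, so the data could hold a return or none.

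Regrouping the arrays tested whether chance can be excluded for the counts of probes at an unadjusted p under 0.05. At 7 days as many probes came up in 13 of 35 splits for dw/dw saline against HZ (758, highest other split 2350), 15 of 35 for GH against saline (534, highest other 1053) and 23 of 35 for GH against HZ (466, highest other 1244). At 30 days they came up in 5 of 35 (820, highest other 1848), 18 of 35 (386, highest other 1244) and 7 of 35 (630, highest other 1842). In both comparisons with HZ at 30 days, the highest of the other splits set replicate 1 of the dw/dw group together with HZ replicates 1, 3 and 4. For the change of the GH effect it was 34 of 100 (592, highest other 1504), for the change of the deficiency effect 49 of 100 (459, highest other 1975) and for the genotype effect 8 of 100 (1102, highest other 2502). Chance cannot be excluded for any of these. For HZ rats at 30 against 7 days, with 264 probes past the adjusted threshold, only 1 of 35 splits, the real one, gave as many. The highest other split gave 1. The share of 0.029 is the smallest that 35 splits can give, and it was not adjusted over the comparisons tested. The real split thus stood apart from the others, but regrouping alone cannot exclude chance here. It cannot exclude a difference between the slides either.

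The first principal component, with 27.9% of the variance, had r = 0.76 with the share of probes detected (permutation p = 3e-05; rho 0.75; 0.79 without the 2 farthest arrays; 0.64 and 0.81 within the slides).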
